A study of Mus musculus with 10 samples.

How the data were processed

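RNA was extracted from sorted AT2 cells with a column kit, and polyA RNA was made into libraries with NEBNext Ultra and sequenced on an Illumina NextSeq 500, per the labels' protocols. The strain is given as C57BL/6 for every sample. The submitters' processing notes name bcl2fastq 2.17, edgeR 3.14.0 and the mouse genome build mm10, without a role or order; the aligner, the annotation release, the strand setting and the exact normalization are not given in the sources used here. The authors deposited 1 table with 16154 Ensembl gene IDs and 10 columns, whose own name calls the values normalized counts, and each column was matched to its sample by its title. The values are a signal that is never negative rather than whole counts, as deposited, and column totals lie between 6.94 and 7.43 M (M for mega), so that depth had already been evened out by the authors.

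Low values in a column fell in clusters near multiples of a step, taken as the value of 1 read, and the clusters had a width of their own. The median of the lowest cluster was 0.531 to 0.908 by library, and between 16.4% and 98.7% of low values were whole multiples of a fitted step within 0.1. Whole reads were therefore not recovered and no count test was run. Dividing each total by its lowest cluster puts the depth at roughly 7.7 M reads (wild type 5) to 13.2 M (wild type 6), and single-gene values below about 1 per M rest on a few reads. In every library 246 genes were listed at 0. Gene symbols were found for 16026 IDs, and 128 IDs had none. Coordinates and exon lengths come from GENCODE release M21, whose assembly is mm10. No column was left unused, no 2 libraries held identical values, and Pearson's r of log2 values between libraries, across genes, was 0.978 to 0.991.

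All values were divided by the mean column total in M (7.14), with no further normalization. Genes with at least 1 per M in at least 5 of the 10 libraries were kept (12946), also where fewer libraries were compared. The main test was limma-trend (limma 3.58.1 in R 4.3.3; lmFit and eBayes with a trend) on log2(value per M + 0.5), two-sided, knockout minus wild type, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + pseudocount) scale, which understates the change of low genes. Rbck1 was also tested by an exact permutation test over the 252 arrangements. Gene lists, 30 in all, were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, and beside it with camera at an estimated correlation and with fry, which asks whether a list moves on balance one way; adjustment was over the lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

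Genes named in the text follow a rule fixed before the data were examined. It takes Rbck1, Prkcz, Hif1a, Epas1, Atp1b1, Rnf31 and Sharpin always, the 10 largest rises and the 10 largest falls among passing genes (leaving out gene models without an official symbol), up to 4 members with the smallest p from each list, and, where fewer than 10 genes pass, the 5 higher and 5 lower genes closest to passing. Repeats in the 8 libraries kept the rule, and genes outside it are said to be so, as are genes that make up a count of 5 or fewer. Some genes that the rule takes are not reported here.

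Groups come from the labels and were never changed. After the Rbck1 values were seen, every result was computed again without the libraries labelled wild type 2 and knockout 1. The mouse numbers in the titles fall into 2 runs, which the labels do not call batches; each run was also analysed alone, and 50 genes differed between the runs (18 higher and 32 lower in the second, with limma). Alternatives fixed in advance were pseudocounts of 0.1 and 2, no filter, a filter at 5 per M, TMM factors, equal totals and median-ratio factors on top of the deposited values, the replicate number as a block, the run as a covariate, sample weights, sex as a covariate without sex-linked genes, and leaving out each library. Removing each library's trend of log2 value on exon length was added later.

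The tests were checked on simulated data drawn for the 12946 genes from the real means, depths and spread, of which 67 were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. For 5 against 5 libraries, 86.6% of the genes changed by 1.5-fold and 100% of those changed by 2-fold and by 4-fold were recovered, with 6 false calls among 197. At 4 against 4, the shares were 80.6%, 92.5% and 100%, with 7 false calls among 189, and for 3 against 2 libraries they were 68.7%, 92.5% and 100%, with 10 among 184. The changed genes were drawn from those with a mean of at least 2 per M, and the simulated genes vary independently and with a smoothed spread. The shares therefore do not hold for every real gene. With all 10 libraries as labelled, Wdfy1 did not pass at a log2 fold change of 1.973.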

Results

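Messenger RNA was measured in alveolar type II (AT2) cells, the surfactant-producing epithelial cells of the lung alveolus, sorted from the lungs of mice aged 8 to 10 weeks. The samples formed 2 groups of 5 libraries each, labelled wild type (replicates 2 to 6) and HOIL-1L knockout (replicates 1 to 5). HOIL-1L is the product of Rbck1 and a subunit of LUBAC, the ubiquitin ligase complex that builds linear ubiquitin chains, and the sources describe the deletion in 2 ways. The genotype label of each knockout sample is HOIL-1L -/-, whereas the design text gives a floxed allele with Cre under the surfactant protein C promoter. Each title carries its own mouse number, so the libraries were taken as separate mice, and these numbers fall into 2 runs. The first run held the libraries labelled wild type 2 and 3 and knockout 1 to 3, and the second held wild type 4 to 6 and knockout 4 and 5. Every title also carries the letter N, which the labels do not explain. It was not used to assign any condition, such as an oxygen level. The deposited values were normalized read counts for 16154 Ensembl genes, with column totals between 6.94 and 7.43 M (M for mega). The lowest values of each column put the depth behind them at roughly 7.7 to 13.2 M reads. Values are given as normalized counts per M, after division of the whole table by 1 constant.

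Rbck1 was examined first in every library because it is the targeted gene. It lies on chromosome 2 (mm10, 152316334 to 152332653, minus strand, protein coding, ENSMUSG00000027466). Among the libraries labelled wild type it stood at 56.1 to 57.8 per M in replicates 3 to 6 and at 29.7 in replicate 2. Among those labelled knockout it stood at 29.8 to 38.8 per M in replicates 2 to 5 and at 59.3 in replicate 1. The library labelled wild type 2 therefore lay at the level of the other knockout libraries and the library labelled knockout 1 at that of the other wild type libraries. Over all libraries as labelled the means were 51.4 ± 12.1 (SD, n = 5) in wild type and 40.5 ± 11.1 (SD, n = 5) in knockout. The difference of mean log2 values, -0.34, was not larger than the spread between libraries (exact permutation test, two-sided, p = 0.206, smallest possible 0.00794). Without those 2 libraries the means were 56.8 ± 0.722 and 35.7 ± 4.06 (SD, n = 4 each), so that the knockout libraries held 62.9% of the wild type level. Within the second run, which holds neither library, the log2 fold change was -0.56 (95% interval -0.80 to -0.33, limma adjusted p = 0.0434), and within the first run as labelled it was -0.03 (limma adjusted p = 0.981). The libraries labelled wild type 2, knockout 2 and knockout 3 were female by Xist and Y-linked genes and the others male, so that within the first run the 3 females (29.7 to 36.4) all lay below the 2 males (56.7 and 59.3), and no other library labelled wild type was female. These gene-level values count all exons of Rbck1, deleted or not, and whether the deletion was constitutive or conditional is not settled by the labels.

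**Figure D1:**
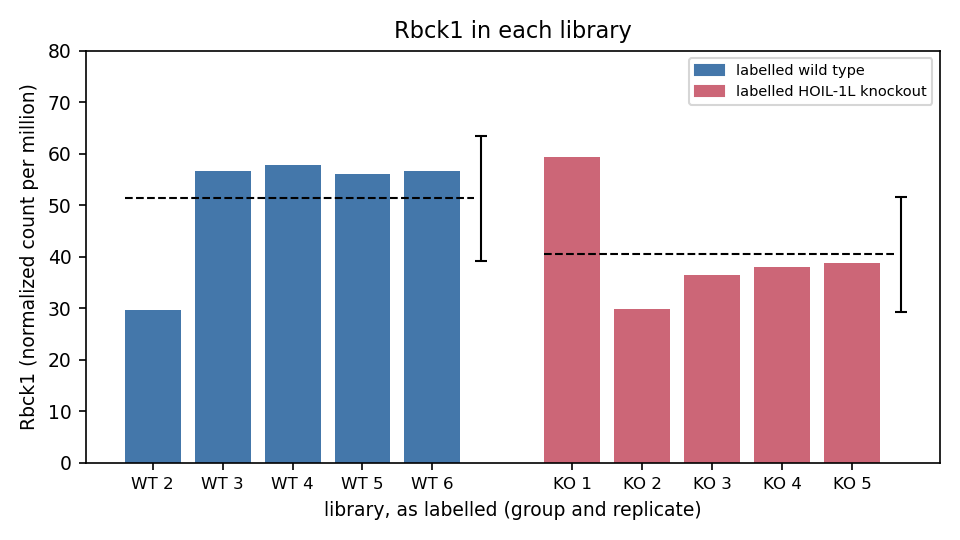
Rbck1 in normalized counts per M (vertical axis, from 0) for each library as labelled (horizontal axis, WT wild type, KO HOIL-1L knockout). Dashed lines are group means over 5 libraries and the bars beside them are 1 SD; WT 2 at 29.7 and KO 1 at 59.3 stand at the level of the other group.

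The main comparison asked which genes differed between HOIL-1L knockout and wild type AT2 cells. With all 10 libraries as labelled, no gene did so beyond the spread between libraries. Of 12946 genes tested, 0 passed an adjusted p of 0.05 with limma, and the smallest adjusted p was 0.269. At an unadjusted p under 0.05 there were 1227 genes, where 647 are expected by chance. The higher genes closest to the threshold were Rnf213 (a large ubiquitin ligase), Trrap (a scaffold of histone acetyltransferase complexes), the noncoding RNA Meg3, Notch2 and Golgb1. Their log2 fold changes ran from 0.35 for Golgb1 to 1.56 for Meg3, with 0.60 ± 0.10 (SE) for Rnf213. On the lower side they were Hist1h1c (a linker histone), the unnamed gene Gm26809, Areg (amphiregulin, a ligand of the EGF receptor), Sprr1a and Mrps24. Hist1h1c stood at 18.6 ± 2.57 in wild type and 11.6 ± 1.65 in knockout (SD, n = 5 each), and the log2 fold change of Areg was -0.86 ± 0.19 (SE). None of these 10 genes passed. Within the first run as labelled the count was also 0, and within the second it was 41. Leaving out the library labelled knockout 1 gave 4 genes, Wdfy1 and Rnf213 higher and Rell1 and Adss lower.

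The series title names Na,K-ATPase, protein kinase C zeta and HIF, and no gene reported here for them passed between the groups. Atp1b1, the beta-1 subunit of Na,K-ATPase, stood at 1210 ± 118 per M in wild type and 1298 ± 102 in knockout (SD, n = 5 each). Prkcz, which encodes protein kinase C zeta, stood at 80.4 ± 2.98 and 84.9 ± 6.74. The 95% interval of its log2 fold change ran from -0.07 to 0.22, which leaves out a change of Prkcz RNA by 1.5-fold either way. For Hif1a the values were 94.0 ± 7.67 and 98.6 ± 6.89, and for Epas1 (HIF-2 alpha) 982 ± 70.9 and 1104 ± 26.5. The other LUBAC subunits, Rnf31 and Sharpin, had log2 fold changes of 0.17 ± 0.10 and 0.08 ± 0.09 (SE). The smallest limma adjusted p among these genes was 0.458, for Epas1. Of the list members tested, 16 of Na,K-ATPase and alveolar ion and water transport, 14 of protein kinase C and AMPK, and 29 of the HIF pathway, 0 passed over all genes and 0 passed adjusted over the list alone. Without the 2 libraries whose Rbck1 level goes against their label, 0 passed over all genes and 7 passed adjusted over the list alone. None of these measurements concerns protein.

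Among the 30 gene lists fixed before the data were examined, 27 had at least 3 tested members. As labelled, 8 passed camera with a preset correlation of 0.01, 2 toward higher and 6 toward lower values in knockout, and no list held a gene that passed over all genes. The oxidative phosphorylation list had 27 of 28 members below 0 and a median log2 fold change of -0.13 (adjusted p = 4.67e-08), with Uqcrc1 at -0.21 and Cox7a2 at -0.32. Adjusted p = 0.833 with an estimated correlation, so that this call rested on the preset value. The NRF2 list, of oxidative stress response genes, had 18 of 21 members below 0 (adjusted p = 9.11e-05, and adjusted p = 0.591 with an estimated correlation). Its members Srxn1 and Nqo1 had log2 fold changes of -0.46 and -0.74, and 2 of its members were lower adjusted over the list alone. The transitional list of genes between AT2 and AT1 cells had Krt8 and Krt18, both keratins, each at -0.27, with 4 members lower adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.833 with an estimated correlation). AT1 cell markers also passed toward lower values (adjusted p = 0.0191), as did cell cycle genes (adjusted p = 0.0123) and fibroblast, smooth muscle and mesothelial markers (adjusted p = 0.0153). With an estimated correlation their adjusted p were 0.833, 0.850 and 0.811. Cholesterol synthesis genes (adjusted p = 0.0123) and type I interferon-induced genes (adjusted p = 0.0191) passed toward higher values, both with adjusted p = 0.850 with an estimated correlation. Without wild type 6 the number of passing lists was 5. Oxidative phosphorylation genes kept their call under every alternative with the preset correlation, and NRF2 genes under all except the first run alone (adjusted p = 0.0502). Each of the other 6 calls was lost, with these adjusted p, when single libraries were left out. For interferon-induced genes these were wild type 3, 5 or 6 or knockout 2 or 3 (0.134 to 0.601), for cholesterol synthesis wild type 4, 5 or 6 or knockout 1 (0.129 to 0.215), and for AT1 markers wild type 5 or knockout 1 or 2 (0.0941 to 0.268). The transitional call was lost without wild type 4 (0.0637) or knockout 4 (0.259), the cell cycle call without wild type 2 (0.673), wild type 3 (0.0698) or knockout 4 (0.127), and the fibroblast call without wild type 6 (0.129) or knockout 3 (0.0713). The interferon list also lost its call with the run (adjusted p = 0.204) or sex (0.554) as a covariate and in the first run alone (0.505), where cholesterol genes passed toward lower values (adjusted p = 0.0292, and adjusted p = 0.872 with an estimated correlation). Without both libraries whose Rbck1 level goes against their label the AT1 (adjusted p = 0.0584), transitional (0.0566), cholesterol (0.0999) and cell cycle lists (0.523, with 13 of 25 members above 0) no longer passed. No list passed with an estimated correlation (smallest adjusted p = 0.591) or with fry (smallest adjusted p = 0.256). AT2 cell markers did not pass (adjusted p = 0.288, 17 of 24 members below 0). Nor did markers of club cells (0.167), ciliated cells (0.311), macrophages and monocytes (0.462) or endothelium (0.804), all as adjusted p. Only 1 lymphocyte, 1 neutrophil and 0 red blood cell markers reached the filter on low values.

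With the 2 libraries left out, a choice made after seeing the data, 52 of the 12946 genes passed with limma, 37 higher and 15 lower in the 4 knockout than in the 4 wild type libraries. Rbck1 is among the 15, but the libraries were left out on its level, so its call there (log2 fold change -0.67 ± 0.09 SE, adjusted p = 0.00167) says nothing further. Among the rises the smallest adjusted p were those of Wdfy1, Nnt, the MHC class I genes H2-Q6 and H2-Q7, and B2m. Wdfy1 (chromosome 1, 79702262 to 79776143), an endosomal adaptor of Toll-like receptor signalling, stood at 11.9 ± 2.88 per M in wild type and 95.2 ± 8.68 in knockout (SD, n = 4 each), a 7.86-fold difference on the log2 scale with pseudocount (adjusted p = 1.77e-09). Nnt (chromosome 13, 119335448 to 119408997), the mitochondrial nicotinamide nucleotide transhydrogenase, stood at 23 ± 3.76 and 66.6 ± 10.9 (adjusted p = 1.1e-05); it was chosen after its values were seen. B2m (chromosome 2, 122147686 to 122153083), the light chain shared by MHC class I molecules, stood at 179 ± 21.1 and 452 ± 115 (adjusted p = 0.000172), and H2-K1, a class I heavy chain, at 1024 ± 118 and 1866 ± 378 (adjusted p = 0.00251). Nlrc5, the transactivator of class I genes, was higher by 1.57 on the log2 scale and Cd59a, an inhibitor of the complement membrane attack complex, by 1.78. Other large rises were those of Camk2b (2.40), Ifi27l2a (2.21), Ly6i (1.84), Meg3 (1.79) and the class I genes H2-Q7 (2.23), H2-Q6 (1.95) and H2-Q5 (1.65), all as log2 fold changes. In wild type 3 to 6, Nlrc5 (0.844 to 2.36 per M), Ifi27l2a (0.549 to 2.65) and Meg3 (0.293 to 1.46) stood near the filter. The rise of Camk2b came from the second run alone. In the first run knockout 2 and 3 stood at 8.13 and 10.5 per M and wild type 3 at 9.50. H2 genes are near-identical copies, and the level of any single one is uncertain because their reads can be shared.

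Among the falls in the 8 libraries, the water channel gene Aqp1 was lower by the most, at 2.94 ± 0.891 per M in wild type and 0.591 ± 0.429 in knockout (SD, n = 4 each), a level near the filter. Sprr1a (-1.51), also near the filter, and Areg (-1.06) followed. Adss, which encodes adenylosuccinate synthase, fell from 61.1 ± 2.42 to 39.7 ± 1.59 (adjusted p = 0.00097), and Rell1 from 26.3 ± 2.68 to 14.9 ± 1.09 (adjusted p = 0.00167). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were lower by 0.74 and 0.63 on the log2 scale, Hist1h1c by 0.71 and Rsrp1 by 0.55. Leaving out 1 more library moved the count of 52 to between 19 (without wild type 5) and 100 (without wild type 6); it was 26 without wild type 4, 32 without knockout 3 and 84 without knockout 4. With sex as a covariate 27 genes passed. All 4 wild type libraries of this comparison were male, and 2 of the 4 knockout libraries female.

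**Figure D2:**
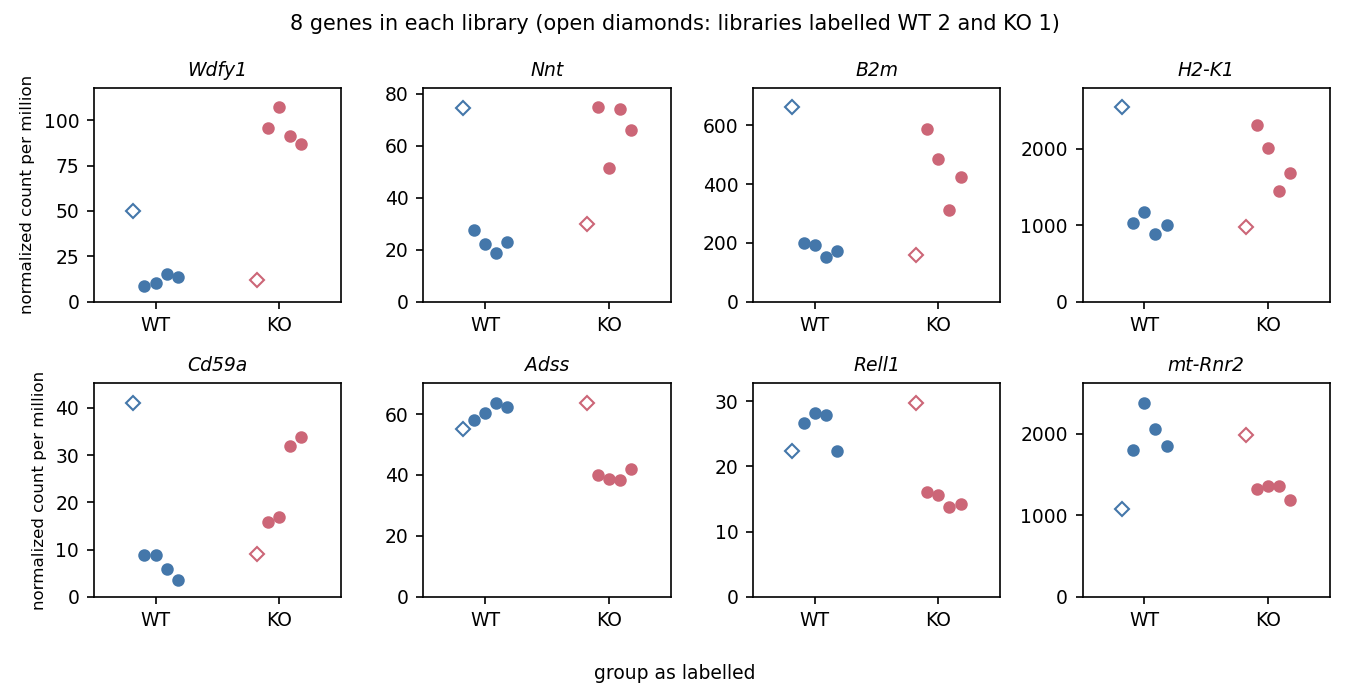
Normalized counts per M (vertical axes, from 0) of 8 genes in each library by group as labelled (horizontal axis, WT wild type, KO HOIL-1L knockout). Filled circles are the 8 libraries compared; open diamonds are the libraries labelled wild type 2 and knockout 1, with Wdfy1 at 50.0 and 11.9 and Nnt at 74.5 and 30.1.

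In the 8 libraries 8 fixed lists passed camera, 4 toward higher and 4 toward lower values. All 13 tested members of MHC class I antigen presentation had positive log2 fold changes, 5 of them passing over all genes and 7 adjusted over the list alone (median 0.47, adjusted p = 1.46e-12, and adjusted p = 0.425 with an estimated correlation). Of 23 type I interferon-induced genes, 21 lay above 0 and 12 were higher adjusted over the list alone, with Bst2, a membrane restriction factor, at 0.78 and Trim30a at 1.08 passing over all genes (adjusted p = 1.02e-10, and adjusted p = 0.425 with an estimated correlation). NF-kB-induced genes passed toward higher values (adjusted p = 0.00234, and adjusted p = 0.425 with an estimated correlation), with 5 members, among them Nfkbiz at 0.49 and Nfkb2 at 0.36, higher adjusted over the list alone. MHC class II genes did so with 0 members passing (adjusted p = 0.0159, and adjusted p = 0.585 with an estimated correlation). Oxidative phosphorylation genes (28 of 28 below 0, adjusted p = 5.33e-07) and NRF2 genes (18 of 21, adjusted p = 0.000378) passed toward lower values, as they had with all libraries. With an estimated correlation their adjusted p were 0.585 and 0.425. Ciliated cell markers (adjusted p = 0.00258) and fibroblast, smooth muscle and mesothelial markers (adjusted p = 0.0434) were also lower as lists, although Msln, a mesothelial gene of the second, was higher by 1.53. With an estimated correlation adjusted p = 0.628 for ciliated markers and adjusted p = 0.585 for the fibroblast list. The ciliated call was lost without wild type 5 (adjusted p = 0.0696), wild type 6 (0.0502) or knockout 3 (0.0881), the fibroblast call without wild type 6 (0.288) or knockout 3 (0.191) or 4 (0.0828), and the MHC class II call without wild type 5 (0.0734) or knockout 3 (0.0768). The AT1, transitional, cell cycle and cholesterol lists, which had passed with all libraries, did not pass here. None of the 8 lists passed with an estimated correlation or with fry (smallest adjusted p = 0.131). Macrophage and monocyte markers did not pass (adjusted p = 0.163), but 9 of 10 members lay above 0 (median 0.28), 1 of them higher adjusted over the list alone, and the only tested neutrophil marker stood at 0.88, higher in the same sense. The interferon-induced Ifi27l2a was highest in the females, at 18.7 and 16.2 per M in knockout 2 and 3 and 16.1 in the library labelled wild type 2, against 5.54 and 2.78 in the male knockout 4 and 5. With sex as a covariate 4 of the 8 lists no longer passed, NF-kB (adjusted p = 0.170), MHC class II (0.263), ciliated (0.442) and fibroblast (0.263), while MHC class I (adjusted p = 3.36e-06), interferon (0.0125), oxidative phosphorylation and NRF2 genes did, and the transitional list passed toward lower values (adjusted p = 0.00211).

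For ion transport, Cftr (log2 fold change 0.55 ± 0.12 SE) and Scnn1a, the alpha subunit of the epithelial sodium channel (0.36 ± 0.09), were higher in the knockout libraries of these 8, and the water channel Aqp5 (-0.22 ± 0.07) lower, when adjusted over the list alone. Of the HIF list the glycolytic genes Hk2 (0.52 ± 0.15) and Pfkfb3 (0.77 ± 0.22) were higher and Ldha (-0.30 ± 0.08) lower in the same sense. These are among the 7 genes of the 3 lists from the title, and over all genes the smallest limma adjusted p of the 7 was 0.0512, for Cftr. With both doubted libraries included 0 members passed. With sex as a covariate 1 did, and leaving out any of wild type 3, 4 and 5 or knockout 2, 3 and 4 left 2 or 3.

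The second run of mouse numbers, 3 wild type and 2 knockout libraries, is a comparison fixed before the data were examined, free of both doubted libraries and all male. It gave 41 genes, 19 higher and 22 lower. Wdfy1 (log2 fold change 2.76), Nnt (1.70), B2m (1.08), Cd59a (2.41) and H2-K1 (0.62) were again higher, and Adss (-0.63), Rell1 (-0.87), Areg (-1.10), mt-Rnr1 (-0.89) and Aqp1 (-2.28) again lower. Camk2b (3.71) was also higher, and its rise in the 8 libraries came from this run alone. These 41 share 25 genes with the 52, all with the same sign, where 0.16 are expected of independent lists; the second run is part of the 8 libraries, so the lists are not independent. Of the 40 genes other than Rbck1, 30 had the same sign between knockout 2 and 3 and wild type 3, libraries of the first run that took no part in the call and that also differ in sex. Of the lists 10 passed, 4 toward higher and 6 toward lower values. The MHC class I list passed here too (adjusted p = 8.66e-07, and adjusted p = 0.538 with an estimated correlation), with 3 members passing over all genes. Of the interferon-induced genes 0 passed, over all genes or adjusted over the list alone, and the list passed with a median of 0.22 (adjusted p = 0.021, and adjusted p = 0.538 with an estimated correlation). The NF-kB list did not pass (adjusted p = 0.216). Cholesterol synthesis genes were higher (18 of 19 above 0, adjusted p = 2.92e-07) and oxidative phosphorylation genes lower (26 of 28 below 0, adjusted p = 3.9e-05), both with adjusted p = 0.538 with an estimated correlation. AT1 markers (adjusted p = 0.000142, 10 of 15 below 0, 3 lower adjusted over the list alone), the transitional list (adjusted p = 0.000608, 10 of 14 below 0) and ciliated markers (adjusted p = 0.000608, 10 of 12 below 0) also passed toward lower values. So did NRF2 genes (adjusted p = 0.000165), and MHC class II genes passed toward higher values with 7 of 7 above 0 (adjusted p = 0.0426). Each of these 5 lists had adjusted p = 0.538 with an estimated correlation. Markers of club cells, another epithelial cell of the lung, were lower in these knockout libraries (9 of 10 below 0, adjusted p = 3.9e-06) and higher in those of the first run as labelled (adjusted p = 9.82e-12). With an estimated correlation adjusted p = 0.538 in the second run and 0.687 in the first.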

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

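All tests of explanations in this part were chosen after the result was seen, except those of called genes within 20 Mb of Rbck1 and of transcript length, and the other splits for the lists as labelled and for the 8 libraries. For these exceptions the prediction came before the result of the test. The removal of length trends and the choice of the 8 libraries were still made after the data were seen. Among 158 groups of 5 values examined for the named genes, 28 held 1 library far from the other 4, where chance gives about 1 in 20, or 7.9. Of these, 19 were in the library labelled wild type 2 and 4 in the library labelled knockout 1. Of these 23, 21 are in the 28 genes named only by their values in the 8 libraries or after being seen (17 in wild type 2 and 4 in knockout 1), a choice that itself makes the 2 libraries left out stand apart, so 7.9 is no measure of chance for them. Among the 51 genes also or only named in other ways 7 of 102 groups held such a value, where chance gives about 5.1, and 2 of the 7, Rbck1 and Scnn1a, were in the library labelled wild type 2.

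In the library labelled wild type 2, Rbck1 stood at 29.7 per M against 56.1 to 57.8 in the other libraries labelled wild type. MHC class I and related genes stood far above the other wild type libraries there, with B2m at 660.2, H2-K1 at 2543 (892 to 1179 in the others), H2-Q4 at 184.4, H2-Q5 at 8.5, H2-Q6 at 123 and H2-Q7 at 140. So did Wdfy1 at 50.0 (8.95 to 15.1), Nnt at 74.5 (18.7 to 27.8), Cd59a at 41.1 and Ly6i at 25.5, the interferon-induced Ifi27l2a at 16.1, Bst2 at 47.1 and Oasl2 at 15.3, and the NF-kB genes Nfkbiz at 21.2 and Nfkb2 at 49.4. The MHC class II genes H2-Ab1 at 1327 and Cd74 at 6174 and the sodium channel gene Scnn1a at 319 complete the 19. In the library labelled knockout 1, Wdfy1 at 11.9 (86.8 to 107 in the other libraries labelled knockout), Rell1 at 29.8 (13.8 to 16.0), Adss at 63.5 (38.3 to 41.9) and mt-Rnr2 at 1982 (1189 to 1355) stood at the wild type level. The remaining values were Sharpin in wild type 5 at 16.8, Lgals3 in wild type 4 at 50.1, Msln in wild type 6 at 8.68, and Otulin at 15.5 and Nqo1 at 3.40 in knockout 5.

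The first pattern is that both of these libraries carry the other group's Rbck1 level. Positions were taken over the 40 genes other than Rbck1 called in the second run, where 0 is the wild type and 1 the knockout mean of that run. The library labelled wild type 2 had a median position of 0.93 (quartiles 0.436 and 1.394) and the library labelled knockout 1 of 0.293 (-0.09 and 0.613). The first-run libraries with no doubt about them gave 0.232 (wild type 3), 0.702 (knockout 2) and 0.806 (knockout 3). In wild type 2, 11 of the 40 genes lay nearer the wild type mean, against 15 in knockout 2 and 6 in knockout 3. In knockout 1, 12 lay nearer the knockout mean, against 10 in wild type 3. Sex is argued against for the library labelled knockout 1, a male, since Rbck1 was lower in the male knockouts of the second run (upper end of the 95% interval of its log2 fold change -0.328). Y-linked RNA in the library labelled wild type 2, 0.255% of the mean of the male libraries, argues against RNA of the other wild type libraries, all male, mixed into it. Such RNA holds more Rbck1 and could not have lowered its level, so this test does not bear on the pattern. For the library labelled wild type 2 sex and a wrong label cannot be told apart, as no other female is labelled wild type and Rbck1 and the positions follow sex throughout the first run, where the highest female Rbck1 value was 0.642 times the lowest male one. In knockout 2 and 3, females, Rbck1 was 29.8 and 36.4 per M, against 38.0 and 38.8 in the male knockout 4 and 5. Wdfy1 was 95.9 and 107 against 91.2 and 86.8, and Nnt 74.8 and 51.4 against 74.2 and 66.0. For Rbck1, Wdfy1 and Nnt these gaps are small beside those between the groups. That does not hold for Ly6i, at 40.49 and 30.25 per M in these females and 9.142 and 13.84 in these males. Wild type 3 to 6 had 4.53 to 5.945 of it. H2-Q7 also differed, at 128 and 95.68 in these females and 47.98 and 74.05 in these males. However, these females and males also differ in run, and they do not show what sex does in wild type. Of the 25 exchanges of 1 wild type with 1 knockout label, exchanging these 2 gave the most called genes, 59. The next (wild type 6 with knockout 1) gave 35, wild type 3 with knockout 4 gave 1 and the other 22 gave 0. An exchange of the 2 labels is therefore a candidate explanation, but not every gene of wild type 2 goes with it. There Adss stood at 55.1 per M, near the other wild type libraries (58.2 to 63.8) and above knockout 2 to 5 (38.3 to 41.9). Rell1 stood at 22.4, within the range of the other wild type libraries (22.4 to 28.2) and above knockout 2 to 5 (13.8 to 16.0). Wdfy1 at 50.0 lay between the groups. A wrong label on knockout 1 alone or 2 separate errors remain open.

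The second pattern is the rise of MHC class I genes, Wdfy1 and Nnt in the knockout libraries once the 2 libraries are left out, where both females are knockouts. Sex is argued against as the whole cause: with sex as a covariate the count of called genes went from 52 to 27, but Wdfy1 (log2 fold change 2.88), Nnt (1.60), B2m (1.02) and the MHC class I list still passed, the largest of their adjusted p being 0.000595, and the all-male second run calls the 3 genes too. Reads shared between H2 copies are argued against as the whole cause, because B2m and Nlrc5 rose and lie outside the H2 family. The 9 list members outside that family were all above 0, though only B2m and Nlrc5 passed over all genes, and Nlrc5 stood near the filter in wild type. Their median log2 fold change was 0.21, at the 99.79th percentile of 10000 random sets matched on level. Those sets draw genes independently, whereas list members can move together, so the percentile can overstate the evidence. A chromosome segment carried along with the targeted allele that holds these genes is argued against for 6 of the 7 (Wdfy1, Nnt and the 5 called members of the MHC class I list), which lie on other chromosomes than Rbck1, but not for B2m, 30.2 Mb from it, and called genes near Rbck1 cannot be told apart from chance, since 0 of the other 51 lie within 20 Mb where 0.99 are expected with no segment at all (one-sided Fisher exact p = 1; the bound of 2% set in advance was too close to the chance share of 1.94%). A strain background that differs between the genotypes cannot be told apart from an effect of the knockout: Nnt and Wdfy1 are known to differ between C57BL/6 substrains, the lowest knockout value was 1.85 times the highest wild type value for Nnt and 5.75 times for Wdfy1, and a background that followed genotype could not be separated from it in these 8 libraries.

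The third pattern is that long genes were higher and the short oxidative phosphorylation genes lower in the knockout libraries, with a Spearman correlation of 0.324 between log2 fold change and exon length across genes, which are not independent replicates. With each library's trend on transcript length removed, the median log2 fold change of the list went from -0.13 to -0.08, and 26 of 28 members stayed below 0. The list still passed (adjusted p = 9.57e-05, camera with the preset correlation). As labelled this call rested on the preset value (adjusted p = 0.833 with an estimated correlation). The pass therefore cannot decide if such a trend is the whole cause. Whether the trend belongs to single libraries rather than to genotype cannot be told apart with 5 libraries a group: the correlation of each library's deviations with length was 0.13 ± 0.131 in knockout and -0.11 ± 0.208 in wild type (SD, n = 5 each, exact permutation test, two-sided, p = 0.0794).

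Other splits of the libraries show what chance can give. As labelled the real count of genes is 0, which all 100 of the splits drawn from the 126 of the 10 libraries had to reach, so the splits say nothing about chance there. The highest count of the others drawn was 35, in a split that put the library labelled knockout 1 with wild type 2 to 5, and the exchange of the 2 labels, a split not drawn, gave 59, which points to a structure of the samples other than the labels. For lists, 48 of the 100 splits drawn gave the 8 lists of the real one or more, and the highest of the others drawn was 16. In the 8 libraries, 1 of the 35 splits, the real one, gave as many as 52 genes, and the highest other count was 8. The 2 libraries left out were chosen on Rbck1 and also stood nearer the other group over many other genes. That choice favours the real split, so the splits do not exclude chance for the gene count. The 8 lists of those libraries were reached by 21 of 35 splits, the highest other count being 12, so chance is not excluded for any count of lists.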

How the results depend on the processing

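All values for the 8 libraries, and the removal of length trends, were chosen after the data were seen. As labelled, the count of genes was 0 under every alternative except the replicate block and the following. It was 1 (Trrap) with the run as a covariate, 41 in the second run alone, 52 without both libraries whose Rbck1 level goes against their label, and 0 to 4 when each library was left out (4 without knockout 1, 0 otherwise). Members of the Na,K-ATPase, PKC and HIF lists passing adjusted over the list alone were 0 as labelled, 1 in the second run, 7 without both libraries and 0 to 5 with 1 library left out (5 without knockout 1, 1 each without wild type 2 and 6). The log2 fold change of Rbck1 stayed below 0 throughout, at -0.56 in the second run, -0.03 in the first and -0.67 without both libraries. Lists passing, 8 as labelled, were 4 with the run as a covariate, 5 (without wild type 6) to 11 (without wild type 2) with 1 library left out, and 0 with an estimated correlation or fry. Some lists turned direction or gained a call. In the first run alone ciliated markers passed upward (adjusted p = 0.00118) and cholesterol genes downward (0.0292). MHC class II genes, which had a downward direction without a call as labelled, passed downward there (0.000647). With an estimated correlation adjusted p = 0.687, 0.872 and 0.687 for these. In the second run alone MHC class II genes passed upward (0.0426) and club cell markers downward (3.9e-06), and cell cycle genes lost their call with a positive direction (0.64); with an estimated correlation adjusted p = 0.538 for the first 2 of these. MHC class II genes passed upward without both libraries (0.0159, and adjusted p = 0.585 with an estimated correlation) and without wild type 2 (0.0149), the other libraries left out giving up to 0.865. The cause of these changes was not tested, beyond the fewer libraries that each fit holds.

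In the 8 libraries the 52 genes became 10 with no filter, where 15908 genes were tested, 27 with sex as a covariate, and 19 (without wild type 5) to 100 (without wild type 6) with 1 library left out. Of the 10, 9 were among the 52, and of the 27, 21 were. The 7 members of the title's lists became 3 with no filter, 1 with sex as a covariate and 2 to 7 with 1 library left out. Lists passing, 8, became 5 with sex as a covariate, 6 (without knockout 3) to 13 (without wild type 3) with 1 library left out, and 0 with an estimated correlation or fry. Scaling hardly mattered: TMM, equal totals and median-ratio factors gave 47, 57 and 47 genes and moved the median log2 fold change of all genes to at most 0.04. Of 1548 values for 78 named genes, 1416 kept their side of the threshold, 99 lost it, 33 gained it and 0 turned direction.

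With the number in the titles as a replicate block, the count was 261 as labelled (210 higher, 51 lower), with 5 members of the title's lists, and 397 in the 8 libraries. A number held by 1 library adds nothing to this comparison. The 261 therefore rest on numbers 2 to 5, without knockout 1 and wild type 6, and the 397 on numbers 3 to 5. Libraries with the same number did not deviate together throughout (correlations of 0.314, 0.027, 0.099 and 0.079 for numbers 2 to 5), and 3 of 8 libraries correlated best with their own number, so the numbers are not taken as pairs. The count tests planned for whole reads were not run because whole reads were not recovered. Depth limits genes near 1 per M, where a value rests on a few reads.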

Other observations

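Sftpc, the surfactant protein C gene that marks AT2 cells, made up 11.2% to 14.3% of each library's total, and the 10 genes highest on average 25.4% to 29.3%. Mitochondrially encoded genes made up 3.33% of the library labelled wild type 2 and 3.78% to 4.09% of knockout 2 to 5, against 4.36% to 5.43% of wild type 3 to 6 and 4.92% of the library labelled knockout 1. Beside the ribosomal RNAs, mt-Nd6 was lower in the knockout of the 8 libraries (log2 fold change -0.52, limma adjusted p = 0.00671), a gene chosen after its values were seen.

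Outside the MHC list, other genes higher in the knockout of the 8 libraries included those of complement C3 (log2 fold change 0.70), the secreted glycoprotein Lgals3bp (0.79), the collagen Col18a1 (0.72), the lysozyme Lyz1 (0.46) and the transcription factor Foxo3 (0.60), and lower ones included cyclin D2 (Ccnd2, -0.50). The second run alone also called 2 collagen VI genes, Col6a1 (0.64) and Col6a2 (0.94), as higher, and Angptl4 (-1.74) and Pdk4 (-1.89), both known targets of fatty acid-sensing nuclear receptors, as lower. All of these were chosen after their values were seen. Chromosome 17, which holds the H2 genes, had 9 of the 51 called genes other than Rbck1.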
